A study of Saccharomyces cerevisiae with 16 samples.

How the data were processed

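Total RNA from 16 samples of *S. cerevisiae* CEN.PK113-7D, 8 from an aerobic and 8 from an anaerobic series, was labelled and hybridized to Affymetrix arrays. Per the labels, biomass was quenched on ice and frozen, RNA was column-purified with DNase treatment, and biotin-labelled cRNA was made from it. The values are log2 intensities that the authors made with GCRMA, which corrects background, normalizes and summarizes to 1 value per probe set. The GCRMA version and options, and whether the aerobic and anaerobic arrays were normalized together, are not given in the sources used here, and the log base was read from the range of the values. No detection calls were analysed here.

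Of 5716 probe sets, 5498 had 1 gene symbol, 0 had several and 218 had none and were left out. For 47 genes with several probe sets, the one of highest mean was used. Of 5449 genes, 5213 reached at least 4 log2 units on at least 3 arrays and were tested, and 236 did not. Of the tested genes 103 lay on probe sets shared with related sequences, and where named they are called shared or uncertain. Where all samples of a side lay under 4 log2 units, the change is given as a bound measured from 4.

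Samples were grouped into early, mid and late from the feed glucose in the labels, before the data were examined. A model of 6 cell means (2 oxygen conditions and 3 phases) was fitted to all 16 arrays with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend, 10 residual degrees of freedom). The contrasts were late minus early in each series, the difference of these changes, the mean anaerobic minus aerobic difference over the phases, and mid against the mean of early and late in each series. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. Gene lists were fixed before the data were examined, and 33 with at least 5 tested members were tested with camera (preset correlation of 0.01 and estimated correlation) and fry. Each list's members were also adjusted over the list alone.

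Named genes followed a rule set beforehand. In each contrast other than those of the mid samples these were the 10 largest positive and 10 largest negative changes among called genes whose sample sets do not overlap, with no such condition for the difference of changes. For the mid samples they were the 5 largest each way. Up to 4 members of largest change were taken from each list described, with a fixed set of 12 marker genes throughout, and not every gene the rule selects is named in the text. Exceptions are stated where they are named.

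Alternatives were no filter or a filter at 6 log2 units, renewed quantile normalization, centring on array medians, the mean of probe sets, other variance models, slopes and splines of feed glucose or sample order, the arrays of each series alone, other phase limits, and leaving out each array. The model was tested on simulated data in which 200 of 5213 genes were changed, 100 by 1 and 100 by 2 log2 units. For late minus early it recovered 56% and 79% in the aerobic and 59% and 89% in the anaerobic series, with 4 and 6 false calls. For the difference of changes it recovered 24% and 68% with 2 false calls, and for anaerobic minus aerobic 78% and 94% with 9. For mid samples it recovered 53% and 86% with 11 false calls in the aerobic series, and 47% and 88% with 8 in the anaerobic series. The simulated noise was normal and independent between samples and genes, with no trend within a phase and no deviating array. These false calls therefore do not give the error rate for serial samples.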

Results

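Gene expression was measured with 16 single-channel microarrays in *Saccharomyces cerevisiae* CEN.PK113-7D, a haploid laboratory strain of baker's yeast much used in physiology. The cells grew on mineral medium with glucose as the limiting nutrient, and the glucose in the feed was then raised linearly until ammonia became limiting. The experiment was done with and without oxygen, and each of these 2 series gave 8 serial samples, numbered 1 to 8 in time. Feed glucose ran from 1 to 60.34 g/L over 53.95 h in the aerobic series and from 1 to 46.75 g/L over 50.85 h in the anaerobic series. In each series the 3 samples of lowest feed glucose were taken as early, the next 2 as mid and the 3 of highest as late. Aerobic early samples had 1, 5.51 and 8.5 g/L, mid samples 11.56 and 16.96 g/L, and late samples 30.97, 47.91 and 60.34 g/L. Anaerobic early samples had 1, 4.87 and 10.31 g/L, mid samples 16.19 and 24.86 g/L, and late samples 33.1, 39.56 and 46.75 g/L. The sample at which ammonia became limiting is not stated in the labels.

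The labels do not say that samples came from separate cultures, so p-values measure only the spread between these serial samples. With 1 series per condition, oxygen and culture cannot be told apart. The number of arrays limits the precision of every value. Values ran from 1.96 to 16.75 log2 units, and 5.42% to 6.74% of probe sets lay under 4 on an array. Array medians lay between 11.33 and 11.51 in the aerobic series and between 10.78 and 10.97 in the anaerobic series. In all, 5213 genes were tested, and ± gives the standard error of a change in log2 units from the limma fit over all 16 arrays.

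The aerobic 9.6 h array (sample 4, 11.56 g/L) stood apart, with a median correlation of 0.870 with the other aerobic arrays, against 0.923 to 0.960 for each of those. The aerobic 0 h array had 0.923 and did not stand apart by this or any other measure screened, while the anaerobic 0 h array did in a few groups of genes given below. The aerobic 0 h array correlated at 0.918 with the 4.1 h array, at 0.960 with the 14.5 h array and at 0.949 with the anaerobic 0 h array. The aerobic 4.1 h and anaerobic 4.35 h arrays correlated at 0.949 too. These correlations are across genes, which are not independent replicates. Counts below are led by the fit with all arrays. They are also given without the 2 arrays at 0 h and the aerobic 9.6 h array, written as "without the 3 arrays", a choice made after the data were seen that moves many counts.

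The first comparison asked how the aerobic cells differed between the low-glucose and the high-glucose end of the series. Late aerobic samples had higher transcript levels of many nitrogen scavenging genes and of most of a list of low-affinity hexose transporters and glucose-induced regulators, and lower levels of many mitochondrial ribosomal protein genes. Part of the iron regulon and of the genes for other carbon sources was lower as well. *OPT2*, a member of the oligopeptide transporter family, rose from under 4 log2 units on each early array to between 15.52 and 15.59 on each late one, a rise of at least 11.56 log2 units (adjusted p = 1.61e-05). *MIG2*, a transcriptional repressor induced by glucose, rose by 7.65 ± 0.85 (adjusted p = 0.000287). *SFC1*, the mitochondrial succinate-fumarate carrier, fell by 8.82 ± 2.12 (adjusted p = 0.0176). Between the 3 early and 3 late aerobic arrays, 807 genes were called, 584 higher and 223 lower.

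Of the 36 targets of nitrogen catabolite repression, the control that silences the use of poor nitrogen sources when a good one is plentiful, 19 rose, 0 fell and 17 were not called. By the same test 24 rose adjusted over the list alone, and without the 3 arrays 28 rose and 2 fell. *DAL80*, which encodes a GATA-type repressor of this pathway, rose by 9.98 ± 1.82 (adjusted p = 0.00473). *DIP5*, the permease for glutamate and aspartate, rose by 9.01 ± 1.59, and *DAL1*, the allantoinase, by 7.71 ± 0.88. The allantoate permease gene *DAL5* rose by 4.44 ± 0.87 (adjusted p = 0.00713), the general amino acid permease gene *GAP1* by 2.61 ± 0.80 (adjusted p = 0.0453) and the ammonium permease gene *MEP2* by 1.19 ± 0.32. The oligopeptide transporter gene *OPT1*, outside this list, rose by 7.27 ± 0.42 (adjusted p = 1.57e-06). *GLT1*, glutamate synthase, rose by 0.83 ± 0.15 and was the single gene called among 8 of ammonium assimilation. The list's median change, relative to the median of 0.10 over all tested genes, was 1.47. The list was called higher by camera with its preset correlation and by fry, but not by camera with an estimated correlation (camera adjusted p = 0.656 with an estimated correlation). Lists given below with such a p were called with the preset correlation, and with the estimated one as well only where its p is under 0.05.

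Of 8 low-affinity hexose transporters and glucose-induced regulators, 6 rose, 0 fell and 2 were not called, and 7 rose adjusted over the list alone. Left without the 3 arrays, 7 rose and 0 fell. *HXT3*, a low-affinity glucose transporter, rose by 5.27 ± 0.83 (adjusted p = 0.0025), and the repressor gene *MIG3* by 4.93 ± 0.94. *HXT1*, a low-affinity transporter gene that was under 4 log2 units on every early array, rose by at least 2.34 log2 units. The camera call for this list was lost when the correlation was estimated (camera adjusted p = 0.392 with an estimated correlation). *HXT7*, a high-affinity transporter whose probe set is shared with a near-identical copy and is therefore uncertain, fell by 0.41 ± 0.12. The values for *SUC2*, which encodes invertase, and *ADH2*, the ethanol-oxidising alcohol dehydrogenase, were -2.06 ± 0.70 and -4.66 ± 1.65 and were not called (adjusted p = 0.0649 and 0.0759). *PDC5*, a minor pyruvate decarboxylase, rose by 3.28 ± 0.39 (adjusted p = 0.000417), and *ALD2*, an aldehyde dehydrogenase, by 2.24 ± 0.63.

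Of 32 genes for carbon sources that glucose represses, 0 rose, 9 fell and 23 were not called, and 11 fell adjusted over the list alone (camera adjusted p = 0.656 with an estimated correlation, fry adjusted p = 0.157), and 4 rose and 16 fell without the 3 arrays. The lactate and pyruvate permease gene *JEN1* fell by 3.72 ± 1.15 (adjusted p = 0.047). Outside the list, *RGI2*, induced in respiratory growth, and *YIG1*, linked to glycerol metabolism, fell to levels under 4 on every late array, with changes of -8.06 and -7.41 log2 units or beyond. *IMA5*, an isomaltase gene, fell by 3.62 ± 0.58. In the respiratory chain 0 rose, 0 fell and 23 were not called of 23, and in the mitochondrial ATP synthase 0 rose, 0 fell and 17 were not called of 17. The value for *CYC1*, the main cytochrome *c*, was -0.52 ± 0.55 and was not called (adjusted p = 0.55).

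Mitochondrial ribosomal protein genes were lower late in the aerobic series. Of 68, 0 rose, 36 fell and 32 were not called, and 64 fell adjusted over the list alone, with a median change relative to all genes of -1.14 (camera adjusted p = 0.563 with an estimated correlation), and 1 rose and 67 fell without the 3 arrays. *MRPL15* and *MRPS17* fell, with changes of -1.56 ± 0.38 and -1.47 ± 0.42. Among 128 cytosolic ribosomal protein genes 0 rose, 0 fell and 128 were not called, and among 80 ribosome biogenesis genes 0 rose, 0 fell and 80 were not called, while without the 3 arrays 0 rose and 103 fell in the first list and 0 rose and 64 fell in the second. Both lists had camera calls with the preset correlation (adjusted p = 0.773 and 0.773 with an estimated correlation). The 9.6 h array, a mid sample, had a ribosome biogenesis mean of 6.44 log2 units against 11.34 to 12.30 on the other aerobic arrays. Of 54 amino acid biosynthesis genes under the activator Gcn4, 0 rose, 10 fell and 44 were not called, 11 fell adjusted over the list alone (camera adjusted p = 0.392 with an estimated correlation), and without the 3 arrays 4 rose and 28 fell. *ASN2*, an asparagine synthetase, fell by 1.22 ± 0.24 (adjusted p = 0.00683).

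Of 20 genes of the iron regulon, 0 rose, 7 fell and 13 were not called, and 8 fell adjusted over the list alone (camera adjusted p = 0.563 with an estimated correlation), with 13 lower and 0 higher without the 3 arrays. *FIT2* and *FIT3*, cell wall mannoproteins that retain siderophore iron, fell, with changes of -5.31 ± 0.93 and -3.67 ± 0.78, and so did *FET3*, the ferroxidase of high-affinity iron uptake, with -3.42 ± 0.79. The metalloreductase family genes *FRE5* and *FRE7* fell to under 4 on every late array, with changes of -3.47 and -2.95 log2 units or beyond. *FET4*, the low-affinity iron transporter, rose by 7.19 ± 0.91 (adjusted p = 0.000632), and *COX5B*, the hypoxic form of a cytochrome *c* oxidase subunit, by 4.44 ± 0.51. *IZH4*, a membrane protein gene linked to zinc, fell by 5.52 ± 1.04. In the phosphate regulon 6 rose, 0 fell and 10 were not called of 16, 8 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.656 with an estimated correlation), and without the 3 arrays 12 rose and 1 fell. *PHM6*, a phosphate-responsive gene, rose by 3.83 ± 0.77. In autophagy and vacuolar proteolysis 4 rose, 0 fell and 29 were not called of 33, 1 rose adjusted over the list alone (camera adjusted p = 0.773 with an estimated correlation), and without the 3 arrays 28 rose and 0 fell. *CPS1*, vacuolar carboxypeptidase S, rose by 2.32 ± 0.53, and *ATG14*, an autophagy gene, by 2.47 ± 0.77 (adjusted p = 0.0488).

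Lists for the 2 mating types and for meiosis were included as a check. The mean of the **a**-cell list was at least 11.59 log2 units on every aerobic array and 11.65 on every anaerobic one. These genes were thus expressed from the start, and their rise alone does not show that other cells appeared. Of the 8 genes on the **a**-cell list, 8 rose, 0 fell and 0 were not called, and 8 rose adjusted over the list alone (camera adjusted p = 0.392 with an estimated correlation), and 8 rose and 0 fell without the 3 arrays. *AGA1*, which anchors the **a**-agglutinin, rose by 2.85 ± 0.50, and the **a**-factor genes *MFA1* and *MFA2* by 2.51 ± 0.44 and 2.03 ± 0.35. Of 3 genes specific to alpha cells, 2 rose and 1 was not called: *MF(ALPHA)1*, the alpha-factor precursor, rose by 7.04 ± 1.07 (adjusted p = 0.00213), *SAG1*, the alpha-agglutinin, by 1.47 ± 0.31, and the value for *STE3*, the **a**-factor receptor, was 1.42 ± 0.66. Of 16 meiosis and sporulation genes 1 rose, 0 fell and 15 were not called. Other large rises were those of *RSB1*, a sphingoid base transporter gene, and *HMS1*, a regulator linked to pseudohyphal growth, both under 4 log2 units on every early array (adjusted p = 0.00022 and 3.13e-08), with at least 5.78 log2 units for *HMS1*.

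The aerobic calls came from limma with Benjamini-Hochberg adjustment, and 374 of the 807 genes changed by at least 1 log2 unit. Early and late samples did not overlap for 804 of the called genes, and for 2477 of all tested genes. Samples in random order would give 10%, but these are the ends of 1 series, and any slow drift separates them. After a second quantile normalization 488 genes were higher and 314 lower. Without the 3 arrays 2841 genes were called, 1726 higher and 1115 lower, and these included all 807. Leaving out 1 array gave 1643 genes without aerobic sample 1, against 313, 278, 343, 337 and 286 without aerobic samples 2, 3, 6, 7 and 8. Of the 33 lists tested, camera called 14 with its preset correlation, 0 with an estimated one, and fry called 8. Of 45 genes named and called here, 13 lost the call without at least 1 of the arrays, and 0 turned. The lists called by fry were the nitrogen catabolite repression targets (adjusted p = 0.0116), ammonium assimilation (0.0372), the low-affinity hexose transporters and glucose-induced regulators (0.000651), mitochondrial ribosomal proteins (0.0372), the Gcn4 targets (0.0145), the phosphate regulon (0.0145), the iron regulon (0.0372) and the a-cell genes (0.00123). In fry a call means that a list's genes move, on balance, one way, and it does not compare the list with other genes.

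**Figure D1:**
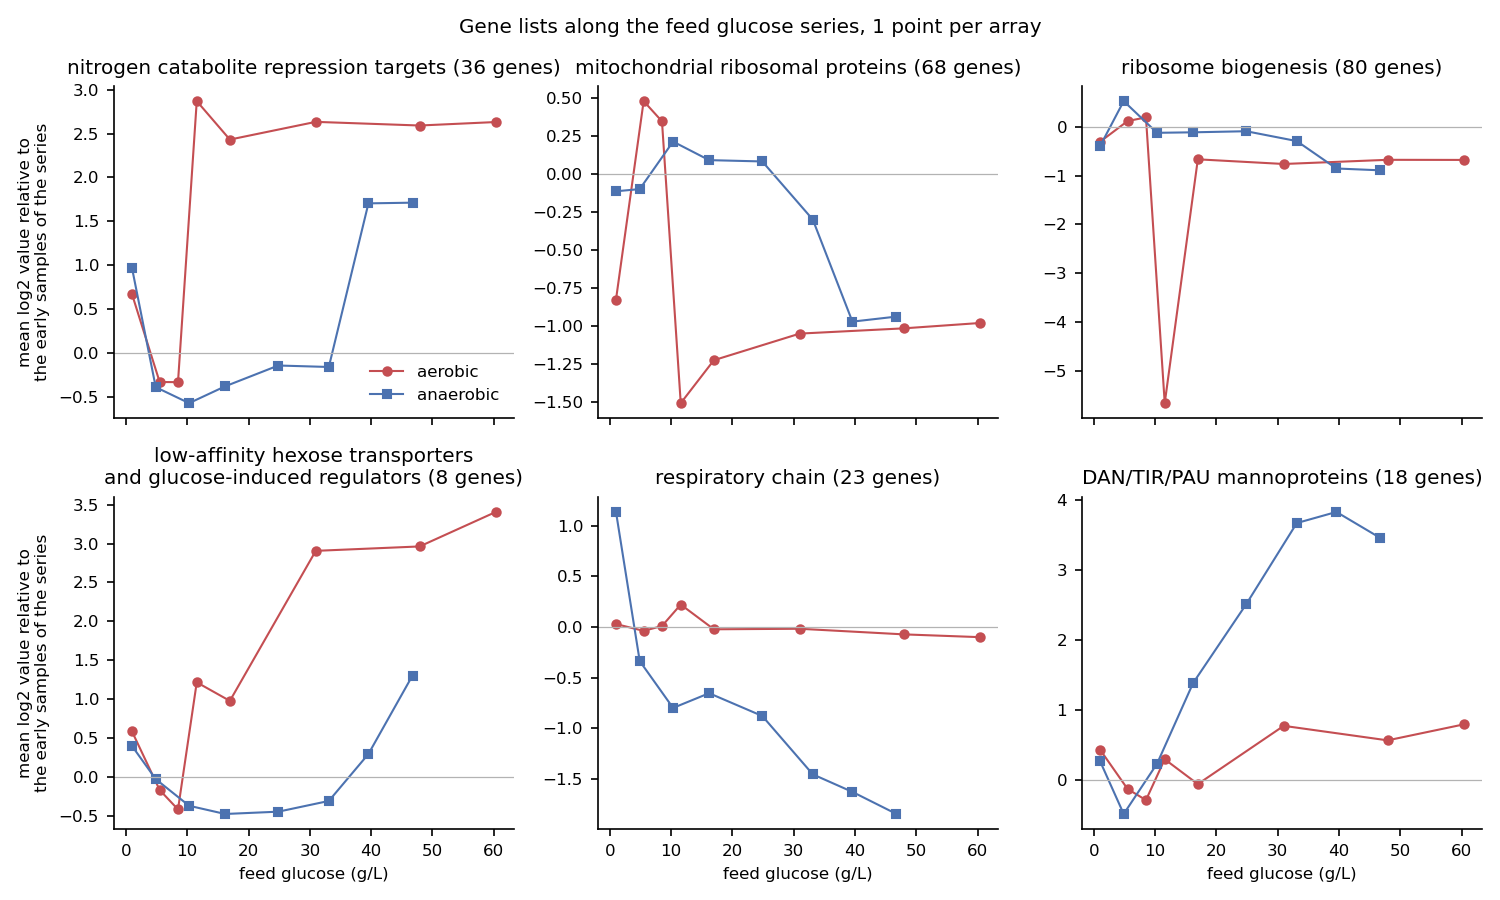
Mean log2 value of 6 gene lists, relative to the mean of the early samples of the same series, against feed glucose in g/L, with 1 point per array (aerobic circles, anaerobic squares). The nitrogen catabolite repression mean rose between 8.5 and 11.56 g/L in the aerobic series and between 33.1 and 39.56 g/L in the anaerobic series, and the ribosome biogenesis mean stood at -5.67 on the aerobic array at 11.56 g/L.

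The second comparison asked the same of the anaerobic series. Late anaerobic samples had higher levels of the cell wall mannoproteins made without oxygen and of some other hypoxic genes, and lower levels of many respiratory chain genes. *PAU5*, a seripauperin cell wall gene, rose by 5.62 ± 0.61 (adjusted p = 0.000616), and *CYC1* fell by 4.18 ± 0.55 (adjusted p = 0.00163). The strongest rise was that of *YML083C*, an open reading frame of unknown function, by 8.10 ± 0.73 (adjusted p = 0.000277). Between the 3 early and 3 late anaerobic arrays, 315 genes were called, 193 higher and 122 lower.

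Of 30 listed *DAN*, *TIR* and *PAU* mannoprotein genes, 18 were tested, and of these 18 rose, 0 fell and 0 were not called. The same held adjusted over the list alone (18 rose) and without the 3 arrays (18 rose and 0 fell). This was the one list of the comparison whose camera call held (camera adjusted p = 0.0146 with an estimated correlation). A gene could pass the filter of 3 arrays through the late anaerobic ones alone, so the count of 18 may be partly built in. With the preset correlation the list was called in 23 of 23 other settings, which included no filter. *TIR4* rose by 4.88 ± 0.50 (adjusted p = 0.000481) and *DAN1* by 4.51 ± 0.98 (adjusted p = 0.0208). *PAU3*, *PAU24* and *PAU2*, on probe sets shared with near-identical family members and so uncertain, rose by 6.87 ± 1.42, 4.90 ± 0.60 and 4.90 ± 1.28. Of 21 other hypoxic and heme-regulated genes, 7 rose, 1 fell and 13 were not called, 14 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.19 with an estimated correlation), and without the 3 arrays 17 rose and 2 fell. *ANB1*, the anaerobic form of translation factor eIF5A, rose by 4.23 ± 0.99 (adjusted p = 0.0277), and the sterol import genes *PDR11* and *AUS1* by 3.94 ± 0.44 and 3.31 ± 0.42. *HEM13*, coproporphyrinogen oxidase, rose by 2.52 ± 0.59 (adjusted p = 0.028), and *HEM14*, the next enzyme of heme synthesis, by 1.58 ± 0.29. In ergosterol biosynthesis 7 rose, 1 fell and 16 were not called of 24, 13 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.467 with an estimated correlation), and without the 3 arrays 18 rose and 2 fell. *ERG24* and *ERG26* rose by 0.85 ± 0.17 and 0.93 ± 0.25, and *HMG1*, an HMG-CoA reductase, fell by 1.09 ± 0.26.

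Of 23 respiratory chain genes, 0 rose, 15 fell and 8 were not called, 20 fell adjusted over the list alone (camera adjusted p = 0.467 with an estimated correlation), and without the 3 arrays 0 rose and 20 fell. *CYB2*, the lactate dehydrogenase that feeds cytochrome *c*, fell by 4.28 ± 1.00 (adjusted p = 0.028), *NDE1*, an external NADH dehydrogenase, fell by 3.93 ± 0.54 (adjusted p = 0.0021), and *CYT1*, cytochrome *c*1, fell by 2.01 ± 0.39. Of 17 ATP synthase genes 0 rose, 5 fell and 12 were not called, 15 fell adjusted over the list alone (camera adjusted p = 0.498 with an estimated correlation), and without the 3 arrays 2 rose and 14 fell. *ATP20*, *INH1* and *ATP19* fell, with changes of -1.48 ± 0.31, -1.30 ± 0.27 and -1.14 ± 0.27. The anaerobic 0 h array moved with these groups: its respiratory chain mean was 14.15 log2 units against 11.17 to 12.68 on the other anaerobic arrays, and its ATP synthase mean 14.57 against 13.12 to 13.82. Its glucose-repressed gene mean was 11.80 log2 units against 8.48 to 9.16, its iron regulon mean 11.01 against 8.77 to 9.69, and its *ADH2* value 11.91 against 4.02 to 7.62. The late change of *ADH2*, -3.79 ± 1.65, was not called (adjusted p = 0.198). Of 32 glucose-repressed genes 0 rose, 2 fell and 30 were not called, and 2 fell adjusted over the list alone (camera adjusted p = 0.631 with an estimated correlation), and 1 rose and 7 fell without the 3 arrays.

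Nitrogen catabolite repression targets gave 4 rises and 0 falls among 36 genes, with 32 not called, while 6 rose adjusted over the list alone (camera adjusted p = 0.631 with an estimated correlation), and 20 rose and 0 fell without the 3 arrays. *OPT2* rose by 3.89 ± 1.00 (adjusted p = 0.0401) and *DAL1* by 3.63 ± 0.88 (adjusted p = 0.0327). The values for *DAL80*, 4.81 ± 1.82, *DAL5*, 2.96 ± 0.87, and *GAP1*, 1.74 ± 0.80, were not called (adjusted p = 0.141, 0.0691 and 0.219). *GAP1* stood at 14.50 log2 units on the 0 h array and between 12.13 and 12.85 log2 units from 4.35 h to 35.67 h. It reached 15.62 and 15.76 on the last arrays. The mean of the nitrogen list moved midway to its late level at 35.5 g/L, yet the late group includes the 33.1 g/L sample. That sample lowers the late mean, so the few calls need not mean a weaker response. Among 68 mitochondrial ribosomal protein genes 0 rose, 1 fell and 67 were not called, 12 fell adjusted over the list alone (camera adjusted p = 0.569 with an estimated correlation), and without the 3 arrays 1 rose and 66 fell. Ribosome biogenesis had 0 genes higher and 0 lower of 80 (camera adjusted p = 0.736 with an estimated correlation), and 0 rose and 76 fell without the 3 arrays. Autophagy and vacuolar genes had 2 higher of 33 (camera adjusted p = 0.631 with an estimated correlation), *APE1* by 1.96 ± 0.49 and *ATG22* by 1.90 ± 0.40, and without the 3 arrays 28 rose and 0 fell. *HXT1* was under 4 log2 units on every anaerobic array.

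In the iron regulon 0 rose, 3 fell and 17 were not called of 20, and 3 fell adjusted over the list alone (camera adjusted p = 0.631 with an estimated correlation). The camera call with the preset correlation was kept in 20 of 23 other settings, and the 0 h mean of the list stood apart as given above. Among the lower genes were *FET3*, with a change of -4.70 ± 0.79, and *ISU1*, an iron-sulfur cluster scaffold gene, with -1.92 ± 0.34. Of 22 fatty acid and phospholipid genes 0 rose, 6 fell and 16 were not called, among them *FAA1*, an acyl-CoA synthetase, and *ELO1*, a fatty acid elongase, with changes of -3.40 ± 0.81 and -1.02 ± 0.24. *SNO1*, a vitamin B6 synthesis gene, fell to under 4 on every late array, with a change of -5.71 log2 units or beyond, the glutamine permease gene *GNP1* fell by 3.13 ± 0.67 and the methionine permease gene *MUP1* fell by 2.89 ± 0.49. *HUG1*, an inhibitor of ribonucleotide reductase, rose by 7.51 ± 0.97 (adjusted p = 0.00147), *HES1*, an oxysterol-binding protein, by 5.30 ± 0.89, *WSC4*, a membrane protein of the stress-sensor family, by 5.60 ± 1.06, and *SET4*, a SET domain gene, by 5.48 ± 1.03. Among the genes of **a** cells 0 rose, 0 fell and 8 were not called of 8 (camera adjusted p = 0.56 with an estimated correlation), among the 3 of alpha cells 0 rose, 0 fell and 3 were not called, and among 16 for meiosis and sporulation 0 rose, 0 fell and 16 were not called.

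Of the 315 genes called by limma in the anaerobic series, 188 changed by at least 1 log2 unit. Early and late samples did not overlap for 314 of the called genes and for 1530 of all tested genes. The 10% for samples in random order is again no fair measure for serial samples. Without the 3 arrays 2120 genes were called, 1091 higher and 1029 lower, and these included all 315. Leaving out 1 array gave 612, 533 and 531 genes without aerobic samples 1, 4 and 5, and 142, 74 and 99 genes without anaerobic samples 2, 7 and 8. Camera called 21 of 33 lists with its preset correlation and 1 with an estimated one, and fry called 5, the mannoproteins (adjusted p = 4.13e-06), other hypoxic genes (0.00101), the respiratory chain (0.012), ergosterol biosynthesis (0.012) and fatty acid and phospholipid synthesis (0.041). Among 37 called genes named for this series, 24 were no longer called when 1 or another array was left out, and 0 turned.

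The changes in the aerobic and anaerobic series overlapped. In both, 92 genes were called, 67 of them higher in both against 21.6 for independent lists, and 20 lower in both against 5.22. The tests of both series shared an estimate of each gene's spread, so genes of small spread are called more readily in both. Independent lists are therefore a loose measure here. Over all tested genes the late minus early changes correlated at r = 0.479, across genes, which are not independent replicates. The 5 genes called in opposite directions were *ARE2*, *HOC1*, *PRM4*, *YGL039W* and *YBL100W-A*, named here after their values were seen. *ARE2*, a sterol acyltransferase gene, was higher late in the aerobic series by 2.40 ± 0.55 and lower late in the anaerobic series, with a change of -2.34 ± 0.55. For each of the 5 the difference between the series was itself called.

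**Figure D2:**
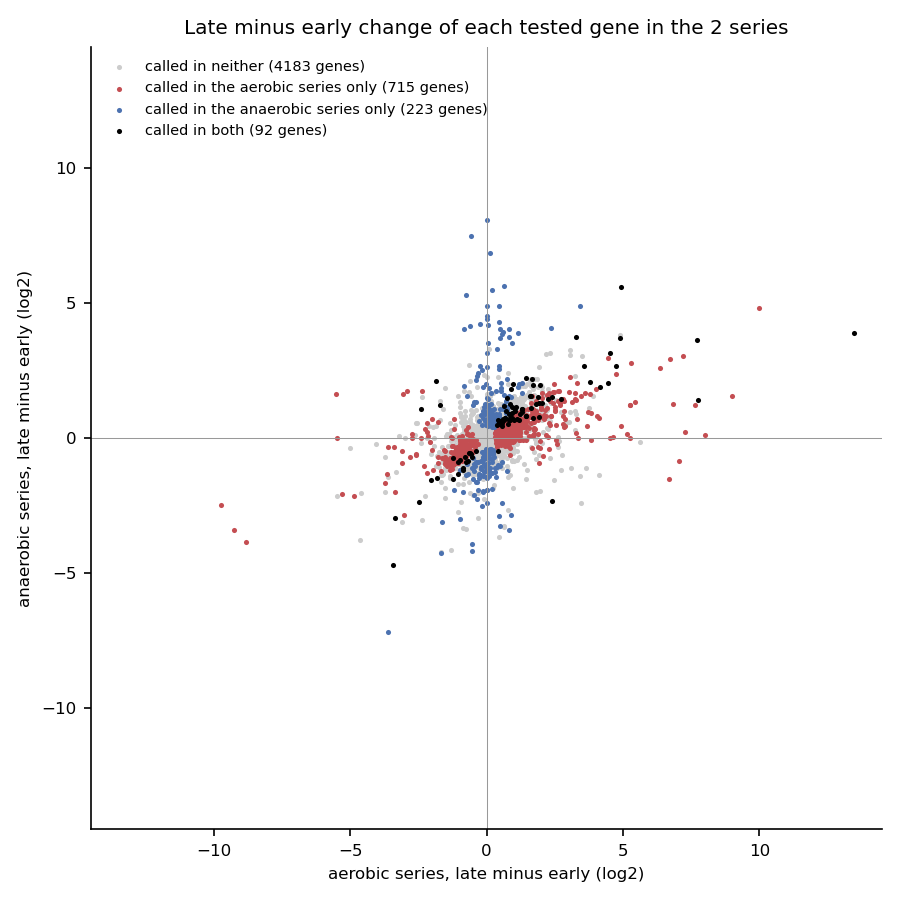
Late minus early change of each tested gene in log2 units, aerobic on the horizontal and anaerobic on the vertical axis, with 1 point per gene coloured by the series in which it was called. Of the genes, 4183 were called in neither series, 715 in the aerobic series alone, 223 in the anaerobic series alone and 92 in both.

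The third comparison tested whether the late minus early change itself differed between the series, as anaerobic minus aerobic. Cell wall mannoprotein genes changed more, towards higher levels, in the anaerobic series, and some respiratory genes moved lower there. In the other direction stood genes with large aerobic rises. *TIR4* had a difference of 4.85 ± 0.71 (adjusted p = 0.00648) and *PAU5* of 4.97 ± 0.87 (adjusted p = 0.0161), while *OPT2* had -9.57 ± 1.42 (adjusted p = 0.00648) and *MIG2* -6.42 ± 1.20 (adjusted p = 0.023). In all, 95 genes were called, 44 with a higher and 51 with a lower anaerobic change.

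Of the 18 *DAN*, *TIR* and *PAU* genes 10 had a higher anaerobic change, 0 a lower one and 8 were not called, against 15 higher and 1 lower adjusted over the list alone. This call held with both correlations (camera adjusted p = 0.0325 with an estimated correlation), and without the 3 arrays the counts were 11 higher and 0 lower. Through the filter these counts too may be partly built in. The value for *DAN1* itself, 4.51 ± 1.39, was not called (adjusted p = 0.136). Of 23 respiratory chain genes 3 had a lower anaerobic change and 20 were not called, against 17 lower adjusted over the list alone (camera adjusted p = 0.689 with an estimated correlation), and without the 3 arrays 11 were lower. *CYC1* and *NDE1* differed by -3.66 ± 0.77 (adjusted p = 0.0364) and -3.38 ± 0.76 (adjusted p = 0.0479). Of 8 low-affinity hexose transporters and glucose-induced regulators 1 was lower, the repressor gene *MIG2*, and 6 adjusted over the list alone (camera adjusted p = 0.425 with an estimated correlation), and 3 without the 3 arrays. The anaerobic mean of these transporters and regulators was highest on the last array, at 9.46 log2 units against 7.68 to 8.56 on the others. The anaerobic feed also ended at 46.75 g/L against 60.34 g/L, so their smaller anaerobic change need not mean a weaker response. Of 36 nitrogen catabolite repression targets 1 differed, *OPT2*, and 2 adjusted over the list alone (camera adjusted p = 0.916 with an estimated correlation), with 1 higher and 3 lower without the 3 arrays. The differences for *GAP1*, *DAL5* and *DAL80* were -0.87 ± 1.13, -1.49 ± 1.23 and -5.17 ± 2.58 (adjusted p = 0.832, 0.66 and 0.395). The anaerobic late group includes the 33.1 g/L sample, taken before this list rose there, so a smaller anaerobic change need not mean a weaker response.

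Other genes with a higher anaerobic change were *YML083C* at 8.10 ± 1.03, *HUG1* at 8.07 ± 1.37, *IZH4* at 7.15 ± 1.47, *HES1* at 6.04 ± 1.26, the multidrug transporter gene *QDR2* at 4.67 ± 1.05, *ECL1* at 4.10 ± 0.87 and the pheromone-regulated gene *PRM4* at 3.98 ± 0.64. The siderophore transporter gene *ARN1* had 3.06 ± 0.62. Those with a lower anaerobic change included *RSB1* at -7.91 ± 1.20, *MF(ALPHA)1* at -7.88 ± 1.51, *OPT1* at -7.05 ± 0.59, *HMS1* at -6.34 ± 0.43, *ARE2* at -4.74 ± 0.78, *PRM6*, another pheromone-regulated gene, at -4.54 ± 0.69, the lipid kinase gene *LSB6* at -3.76 ± 0.79, *MUP1* at -3.33 ± 0.70 and *PDC5* at -3.09 ± 0.55. The early or late means behind *DAN1*, *YML083C*, *HUG1*, *IZH4*, *HES1*, *QDR2*, *OPT2*, *RSB1*, *HMS1* and *PRM6* lay under 4 log2 units in at least 1 series, so the size of these differences depends on the floor of the arrays. Of the 8 **a**-cell genes 0 were called (camera adjusted p = 0.849 with an estimated correlation), of the 3 alpha-cell genes 1 had a lower anaerobic change, and of 16 meiosis genes 1 had a lower one.

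With limma 87 of the 95 genes differed by at least 1 log2 unit, and 509 genes were called without the 3 arrays, 197 higher and 312 lower. Leaving out 1 array gave 186, 37, 44, 45, 27 and 32 genes without aerobic samples 1, 2, 3, 6, 7 and 8, and 39, 233, 35, 28 and 62 without anaerobic samples 2, 3, 6, 7 and 8. Camera called 12 of 33 lists with its preset correlation, 1 with an estimated one and 7 without anaerobic sample 6, and fry called 2, the mannoproteins (adjusted p = 0.000915) and the hexose transporters and regulators (0.0135). The call ended on leaving out at least 1 array for 14 of the 23 called genes named, and 0 turned.

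The fourth comparison set the anaerobic against the aerobic series over all phases, with 8 arrays in each. The anaerobic series had higher levels of *DAN*, *TIR* and *PAU* genes and other hypoxic genes and lower levels of genes for respiration, peroxisomal oxidation and the iron regulon. *DAN1* and *TIR1* lay under 4 log2 units on every aerobic array and were higher by at least 9.92 and 10.86 log2 units in the anaerobic series (adjusted p = 4.12e-08 and 3.8e-09). *MLS1*, malate synthase of the glyoxylate cycle, was lower, with a difference of -6.79 ± 1.04 (adjusted p = 9.61e-05). In all, 3663 genes were called, 417 higher and 3246 lower, but the median difference over all genes was -0.51 log2 units, and list medians are given relative to it. A second quantile normalization gave 1229 higher and 1302 lower, and centring on array medians 1553 higher and 1215 lower.

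All 18 tested mannoprotein genes rose, under each of these scalings and without the 3 arrays. Their median relative to all genes was 5.68 (camera adjusted p = 0.00446 with an estimated correlation). Members under 4 log2 units on every aerobic array, such as *DAN1* and *TIR1*, passed the filter only through the anaerobic arrays. The count of 18 is therefore partly built in. *TIR4* was higher by 7.53 ± 0.31, and *PAU24* and *PAU4*, on shared probe sets, by 8.75 ± 0.37 and 6.23 ± 0.26. Of 21 other hypoxic genes 15 rose, 3 fell and 3 were not called, with a relative median of 2.26 (camera adjusted p = 0.0238 with an estimated correlation), against 15 and 18 higher under the other scalings and 17 without the 3 arrays. *ANB1* was higher by at least 8.93, *AAC3*, the anaerobic ADP/ATP carrier, by 7.66 ± 0.61, *ATF2*, an alcohol acetyltransferase, by 4.71 ± 0.75, *FET4* by 4.88 ± 0.57 and *HEM13* by 2.66 ± 0.37. In heme synthesis 5 rose, 1 fell and 2 were not called of 8 (camera adjusted p = 0.0769 with an estimated correlation), against 7 higher under either other scaling, and in glycolysis 10 rose, 0 fell and 6 were not called of 16, with a relative median of 0.72 (camera adjusted p = 0.166 with an estimated correlation) and 5 and 13 higher under the other scalings. *HXK1*, a hexokinase, was higher by 0.87 ± 0.18. *HES1*, *INA1* and, by at least 5.53 log2 units, *COS10* were other genes with large rises, *HES1* by 9.87 ± 0.56 and *INA1* by 6.03 ± 0.28.

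Respiratory genes fell: 23 of 23 in the respiratory chain, 16 of 16 in the tricarboxylic acid cycle and 17 of 17 in the ATP synthase, the same counts as without the 3 arrays. Their relative medians were -1.22, -0.60 and -0.40, and the camera calls were lost with an estimated correlation (adjusted p = 0.648, 0.648 and 0.683). After quantile normalization 22, 15 and 14 fell, and after centring 22, 10 and 7. *CYC1*, *NDE1* and *CYB2* fell, with differences of -2.52 ± 0.34, -3.62 ± 0.34 and -4.95 ± 0.63, and *SDH2*, a subunit of succinate dehydrogenase, fell by 1.54 ± 0.26. Of 32 glucose-repressed genes 3 rose, 23 fell and 6 were not called, with 17 and 20 lower under the other scalings. *SFC1*, *FBP1*, the gluconeogenic fructose-1,6-bisphosphatase, and *ADH2* fell, with differences of -7.63 ± 1.32, -7.34 ± 0.98 and -6.57 ± 1.03. Of 18 genes of peroxisomal beta-oxidation 1 rose, 17 fell and 0 were not called, among them *CTA1*, peroxisomal catalase, which fell by 6.98 ± 1.39, and 14 and 16 were lower under the other scalings. Camera did not call these last lists. *SUE1*, a gene for the turnover of cytochrome *c*, fell by 8.79 ± 0.93, and *SOD2*, mitochondrial superoxide dismutase, fell by 3.10 ± 0.35.

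Of 20 iron regulon genes 0 rose, 17 fell and 3 were not called, with a relative median of -1.13 (camera adjusted p = 0.648 with an estimated correlation) and 16 lower under either other scaling. *HMX1*, heme oxygenase, fell by 6.75 ± 0.75. Of 36 nitrogen catabolite repression targets 2 rose, 26 fell and 8 were not called, with 21 and 17 lower under the other scalings, and camera did not call the list. *PUT4*, the proline permease gene, and *DAL5* fell, with differences of -6.97 ± 1.12 and -3.08 ± 0.54. The mean of this nitrogen list moved midway to its late level at 10.1 g/L in the aerobic and at 35.5 g/L in the anaerobic series. The phases compared were thus not matched for its rise, and a lower anaerobic level need not be an effect of oxygen. *ARO9*, an aromatic aminotransferase gene, fell by 7.07 ± 0.82, and *ARO10*, a phenylpyruvate decarboxylase gene under 4 on every anaerobic array, with a difference of -4.25 or beyond. All 34 proteasome genes were called lower, but the relative median was -0.07, 23 were lower after quantile normalization, and after centring 3 were higher and 6 lower. Mitochondrial ribosomal protein genes turned direction with the scaling, from 0 higher and 21 lower of 68 to 13 higher and 3 lower after quantile normalization and 15 higher and 1 lower after centring. Cytosolic ribosomal protein genes had 44 higher and 1 lower of 128, but 0 higher adjusted over the list alone (camera adjusted p = 0.407 with an estimated correlation), against 36 higher after quantile normalization and 124 after centring. Their relative median was 1.04, and their mean on the aerobic 9.6 h array was 12.25 log2 units against 14.51 to 15.14. Without the 3 arrays 77 were higher. Of the **a**-cell genes 0 rose, 3 fell and 5 were not called of 8, with 1 lower under either other scaling, of the alpha-cell genes 1 of 3 fell under each scaling, and of the meiosis genes 2 rose, 6 fell and 8 were not called, the last turning to 5 higher and 2 lower after quantile normalization.

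Of the 3663 genes called by limma, 1242 differed by at least 1 log2 unit, 167 higher and 1075 lower, and the 8 arrays of each series did not overlap for 1155 genes of all those tested. Without the 3 arrays 4129 genes were called, 557 higher and 3572 lower. No array left out moved the total by more than 1.5 times (3389 to 4081), but without aerobic sample 5 the genes called higher rose from 417 to 800, with 3281 lower. Camera called 17 of 33 lists with its preset correlation and 2 with an estimated one, and fry called 22. Leaving out at least 1 array ended the call for 0 of 30 called genes named, with 0 turned.

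**Figure D3:**
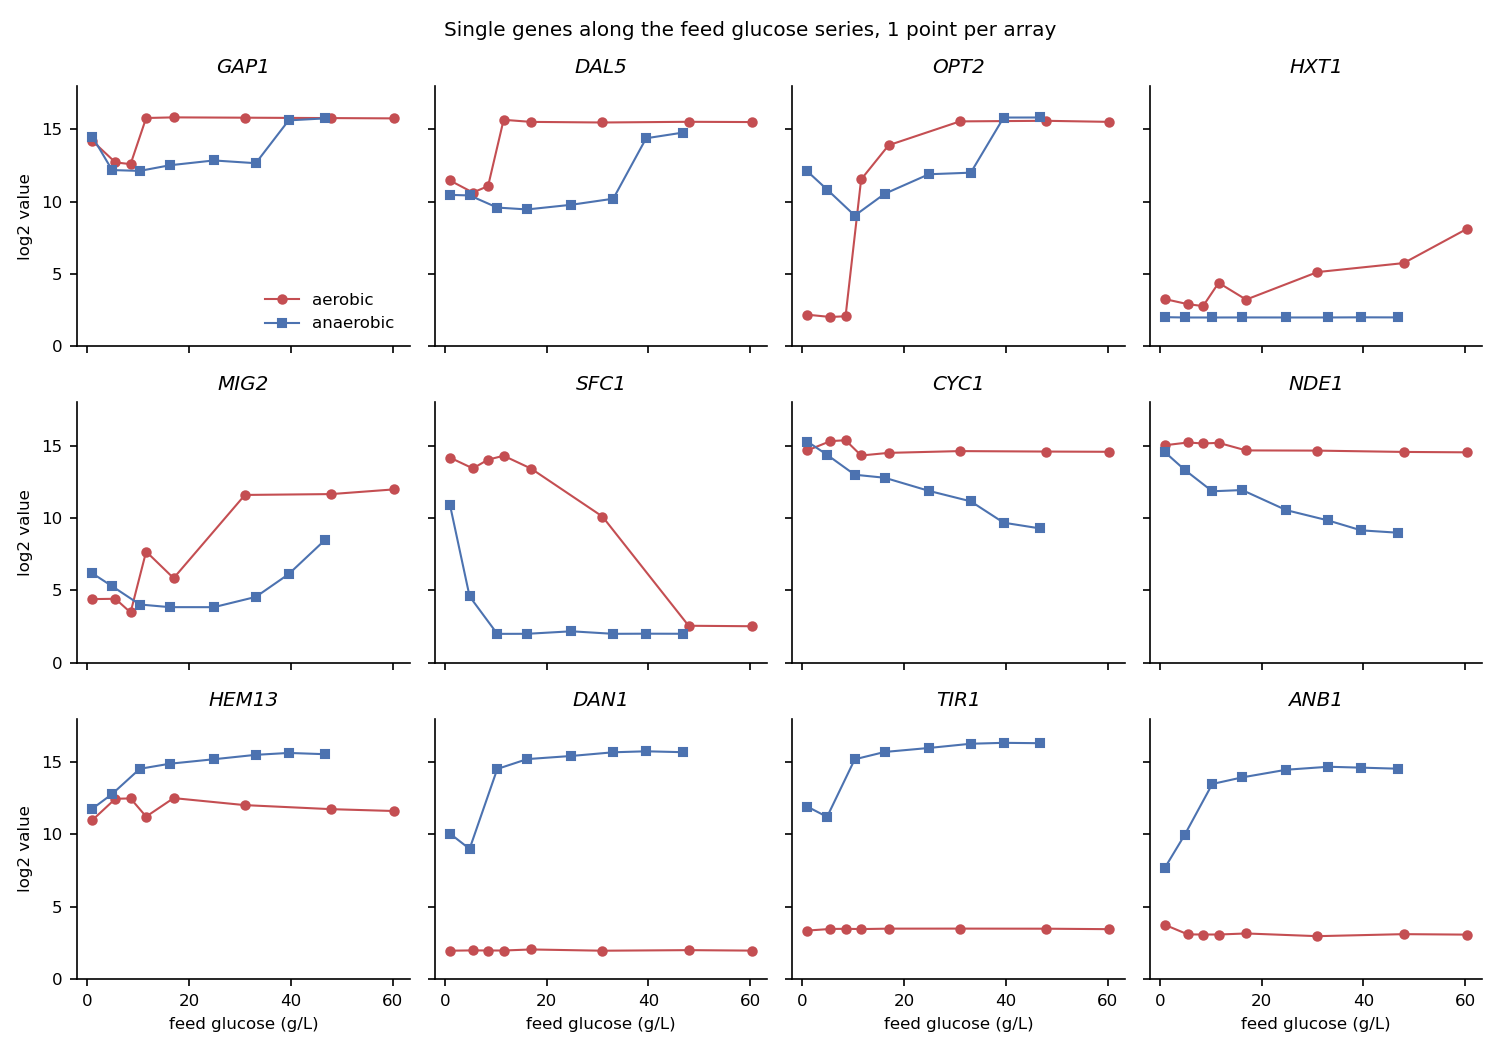
Log2 value of 12 genes against feed glucose in g/L, with 1 point per array (aerobic circles, anaerobic squares). *GAP1* and *DAL5* stood at 15.48 log2 units or more from 11.56 g/L on in the aerobic series and reached their highest levels from 39.56 g/L on in the anaerobic series, and *DAN1*, *TIR1* and *ANB1* lay under 4 log2 units on every aerobic array.

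The last comparison looked for genes whose mid samples differed from the mean of the early and late ones. In the aerobic series 33 genes were called, 5 higher and 28 lower. *PHO84*, the high-affinity phosphate transporter gene, was lower in mid samples, with a difference of -5.03 log2 units or beyond (adjusted p = 0.000861), at 3.11 and 3.18 against 7.37 to 9.98 on the other aerobic arrays. *SRP40*, a nucleolar protein gene, and *ARG80*, a regulator of arginine metabolism, had differences of -5.07 ± 0.89 and -3.72 ± 0.64, while *QDR1*, a multidrug transporter gene, and *COS12* were higher by 2.25 ± 0.41 and 2.24 ± 0.34. Of these 5 genes 4 lost the call when some array was left out, and *SRP40*, for 1, lay at -2.74 without aerobic sample 4 (adjusted p = 0.144) and at -7.40 without sample 5. With 2 mid arrays the count rested on single arrays: it was 1756, 3, 6, 7, 1654, 10, 2 and 3 without aerobic samples 1 to 8 in turn (of the 7 without sample 4, 1 was among the 33), and 8, 8, 68, 4 and 3 without anaerobic samples 4 to 8. A second quantile normalization gave 619 genes, 278 higher and 341 lower, a quadratic term of sample order 0, and the fit without the 3 arrays 710. At an unadjusted limma p under 0.05 there were 1872 of 5213 genes in the aerobic series and 99 in the anaerobic series. The 99 are under a share of 0.05 of the genes and so are no sign of change. In the anaerobic series limma called 0 genes, and 25 were called with a quadratic term of sample order. Leaving out anaerobic sample 3 or 6 gave 5 or 3.

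The feed glucose at which a list mean had moved midway from its early to its late level was read by interpolation, as a description with no test. For the nitrogen catabolite repression targets it was 10.1 g/L in the aerobic and 35.5 g/L in the anaerobic series, and over single arrays left out it ran from 8.77 to 13.5 g/L (without aerobic sample 4) and from 32.8 (without anaerobic sample 6) to 37.1 g/L. For mitochondrial ribosomal proteins it was 9.91 g/L (8.78 to 13.1) and 33.8 g/L (32.7 to 34.3). For the anaerobic mannoproteins it was 19.6 g/L, with a range of 19.1 to 20.5 g/L, and for the other hypoxic genes 11.6 g/L (11.3 to 13.9) in the anaerobic series. The list of low-affinity hexose transporters and glucose-induced regulators reached it at 21.1 g/L (15.3 to 26.5) in the aerobic series. Ribosome biogenesis reached it at 8.78 g/L on the way to the low mean of the 9.6 h array, and at 13.9 g/L without it.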

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

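Every test of the patterns weighed here was chosen after the result was seen, apart from the gene length test and the other splits of the samples.

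In a screen of 93 pairs of series and measure, 13 had 1 sample far from the other 7, judged by its gap to the nearest sample as a share of the whole range. For independent normal samples chance gives about 1 in 20. These samples are serial and the measures are related, so the 13 cannot be weighed against that share. The aerobic 9.6 h sample stood apart in median correlation with its series (share 0.591, 0.870 against 0.923 to 0.960) and in the means of 6 lists. These were the respiratory chain (0.598, 14.39 log2 units against 14.07 to 14.20), cytosolic ribosomal proteins (0.784, 12.25 against 14.51 to 15.14), ribosome biogenesis (0.837, 6.44 against 11.34 to 12.30), translation factors (0.667, 12.63 against 13.58 to 14.06), sulfate assimilation (0.694, 12.97 against 13.55 to 13.81) and purine biosynthesis (0.662, 12.13 against 13.40 to 14.04). The anaerobic 0 h sample stood apart in glucose-repressed genes (0.796, 11.80 against 8.48 to 9.16), peroxisomal beta-oxidation (0.727, 11.81 against 8.52 to 9.42), the iron regulon (0.590, 11.01 against 8.77 to 9.69) and *ADH2* (0.544, 11.91 against 4.02 to 7.62). The anaerobic 4.35 h sample stood apart in glycolysis (0.564, 14.98 against 15.25 to 15.45) and the proteasome (0.581, 13.00 against 13.23 to 13.40).

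The late minus early changes differed between the series for 95 genes and 12 lists, by a test of the difference itself. Of 100 splits of the samples, 3 called as many genes, the real one included. That share is under 0.05, but it does not exclude chance, since serial samples with trends are not exchangeable. Splits that break the order put the trend into the spread between samples. The 2 others called 1223 and 502 genes, several times the real count. In the first, the early aerobic samples took the late place together with anaerobic samples 1, 7 and 8. In the second the late aerobic samples kept theirs beside anaerobic samples 1, 3 and 6. Both kept the real grouping of the aerobic series, so its late minus early change enters their counts. Of these 100 splits, every one that called any gene kept the real grouping of at least 1 series. For the lists 91 of 100 splits called as many, up to 26, so chance cannot be excluded. For late minus early the 10 splits of each series are too few for a share under 0.05. The aerobic count was 807 genes, with 1 split as large and 0 in the highest other, and the anaerobic count 315, with 1 split as large and 3 in the highest other. For lists, 5 aerobic splits called as many as the 14, up to 18, and 1 anaerobic split as many as the 21, with 19 in the highest other. For anaerobic minus aerobic, 1 of 100 splits called as many as 3663 genes, with 2918 in the highest other, but these splits cannot exclude chance. They move samples between 2 single series whose array medians do not overlap, so any difference between the cultures would favour the real split. As for lists, 40 of these splits called as many as the 17, up to 22. Camera with a preset correlation thus called many lists in arbitrary splits, and its counts carry little weight here.

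Ribosome biogenesis genes were low in the aerobic 9.6 h sample. A dim or differently normalized array would lower genes of like level as well, but after renewed quantile normalization the list fell by 5.01 log2 units more than random lists matched on level. Loss of long transcripts in degraded RNA would lower genes of like length, but the list fell by 5.80 log2 units more than the median of 10000 random lists matched on length. An acute response to running out of ammonium may be a candidate explanation and stays open, since the anaerobic list mean at 39.56 g/L, the first sample after the nitrogen genes rose there, differed by 0.038 log2 units from that at 46.75 g/L and the sampling may have missed a brief fall. Handling of this 1 sample was not tested.

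Hypoxic genes outside the cell wall were lowest in the anaerobic 0 h sample (list mean 11.09 log2 units against 11.47 to 13.10), but the mannoproteins were not, with means of 11.14 at 0 h, 10.39 at 4.35 h and 11.11 at 10.38 h. A swap of the 0 h labels is argued against by the mannoprotein list, whose mean at anaerobic 0 h lay 3.13 log2 units above the highest aerobic one, while a test on 7 single genes, 28.6% of them above 4 log2 units at aerobic 0 h, had too few genes to decide. A share of aerobic RNA in the sample would lower 5 genes alike that lay under 4 on all aerobic arrays, and their interquartile range of 2.53 log2 units comes from too few genes to decide. Other values leave it open as well: the respiratory chain and ATP synthase means of the sample, 14.15 and 14.57 log2 units, lay within those of the aerobic arrays (14.07 to 14.39 and 14.52 to 14.75), and its correlation of 0.949 with the aerobic 0 h array was above those with the anaerobic arrays (0.934 to 0.948). Adaptation to anaerobic growth still under way, or an effect of the rising feed, stays open: 100% of these 5 genes were at least 1 log2 unit higher at 10.38 h than at 0 h, but the fall of the mannoprotein mean from 0 h to 4.35 h goes against a steady adaptation from 0 h. Time and feed rise together and cannot be told apart.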

How the results depend on the processing

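The settings without the 0 h and aerobic 9.6 h samples were chosen after the data were seen. Filters, the mean of probe sets, centring and other variance models left every total gene count of the 6 comparisons within 1.5 times its value, as did renewed quantile normalization except for aerobic mid samples (619 genes). The genes higher in anaerobic minus aerobic went from 417 to 1553 with centring and to 1229 with renewed quantile normalization. The aerobic late minus early count was 171 with a slope on feed glucose, 258 with a slope on sample order, 163 with a spline, 476 from the 8 aerobic arrays alone and 8 with the 2 lowest against the 2 highest feed levels. The anaerobic count was 120 from its own arrays and 127 with the 2 lowest against the 2 highest levels, which gave 13 for the difference of changes. Mid samples with a quadratic term gave 0 (aerobic) and 25 (anaerobic). A minimum change of 1 log2 unit left 374 (aerobic), 188 (anaerobic) and 1242 (anaerobic minus aerobic), by construction. Lists called with an estimated correlation were 0, 1, 1 and 2 for the aerobic, anaerobic, difference and oxygen comparisons, and fry called 8, 5 and 2 in the first 3. Without the 0 h samples the counts were 2010, 1038, 205 and, for aerobic mid samples, 2223. Without the 0 h and aerobic 9.6 h samples they were 2841, 2120, 509 and 710. Leaving out single arrays gave 278 to 1643 (aerobic), 74 to 612 (anaerobic), 27 to 233 (difference), 3389 to 4081 (anaerobic minus aerobic), 2 to 1756 (aerobic mid) and 0 to 5 (anaerobic mid). For lists the ranges were 14 to 20, 18 to 22, 7 to 14 and 17 to 19. The nitrogen catabolite repression midpoint ranged from 8.77 to 13.5 g/L in the aerobic and from 32.8 to 37.1 g/L in the anaerobic series. Apart from settings that use fewer samples or a stricter minimum, the cause was not tested. Named genes gave 4453 values under other settings: 3874 kept their side of the threshold, 551 lost the call and 28 gained it. Of the values called in either fit, 0 changed direction. Direction was not compared for values called in neither fit, and some of these changed sign. The difference of changes ran from -2.31 to 0.877 for *DAL5* and from -1.41 to 0.495 for *GAP1*. No paired analysis was possible because the samples of the aerobic and anaerobic series share only their order. Signal over background limits genes near the floor: 5.42% to 6.74% of probe sets lay under 4 log2 units on an array.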

Other observations

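The tests of the alpha-factor gene below were chosen after its values were seen. Of 15 thiamine biosynthesis genes 4 rose, 1 fell and 10 were not called between early and late aerobic samples, and 9 rose and 2 fell adjusted over the list alone, but camera did not call the list (adjusted p = 0.0618). The thiamine transporter gene *THI7* rose by 1.69 ± 0.30. Of 25 genes of sulfate assimilation and methionine 0 rose, 2 fell and 23 were not called: *MHT1*, which uses S-methylmethionine, and *MMP1*, which imports it, with changes of -2.29 ± 0.32 and -1.66 ± 0.33. Camera did not call this list either (adjusted p = 0.0771). Of 43 stress and heat shock genes 1 rose, 2 fell and 40 were not called, and of 21 storage carbohydrate genes 0 rose, 0 fell and 21 were not called, while 28 rose and 2 fell and 15 rose and 1 fell without the 0 h and aerobic 9.6 h samples. The small heat shock gene *HSP12* had 2.33 ± 1.06 and was not called by limma (adjusted p = 0.153).

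The alpha-factor gene *MF(ALPHA)1* stood between 5.27 and 6.07 log2 units in the aerobic series up to 9.6 h, at 10.54 at 14.5 h and between 12.60 and 13.00 in the late samples. In alpha cells *SAG1* and *STE3* would rise alike, but the smallest gap between their changes and that of *MF(ALPHA)1* was 5.57 log2 units, and their high early levels of 9.37 and 7.21 would hide a small share of such cells, so this stays open. Of 22 pheromone response genes, listed after the alpha-factor change was seen, 16 were called higher (72.7%) and 1 lower, with a median change of 1.03 log2 units, against 584 higher and 223 lower of all 5213 tested genes. Among the 22 *FUS1* rose by 2.88 ± 0.29, *FIG1* by 3.78 ± 0.60 and *FAR1* by 2.25 ± 0.35, and *PRM5* fell by 2.74 ± 0.37. The list was not tested for enrichment, and that these genes rose together does not show why, so a response to pheromone stays open as well. No other explanation was tested.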
